A study of Mus musculus with 4 samples.

How the data were processed

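Total RNA from mouse germline stem cells, spermatogonial stem cells grown in culture, was measured on 4 Agilent 1-colour arrays of the 60-nucleotide whole mouse genome design 014868. The cells carried a recombinase that 4-hydroxytamoxifen switches on and a construct that expresses tagged Nanos2 once the recombinase has acted. Per the labels' protocols, the cells grew on mitomycin-treated embryonic fibroblasts with GDNF at 20 ng/ml, EGF at 20 ng/ml and FGF2 at 10 ng/ml, took DMSO or 4-hydroxytamoxifen for 48 hours, and were freed of feeder cells before RNA was extracted. Cy3-labelled RNA was made from 0.20 µg of total RNA, per the labels' protocols.

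The deposited scanner files hold intensity values for each spot on a linear scale: processed signals, mean signals, local background signals and flags. Per the file headers, Agilent Feature Extraction 10.7.3.1 subtracted the background and detrended the signal within each array. The submitters' processing notes name version 9.5 of that program, a conflict that the sources used here leave open. A deposited value table of the same arrays holds log2 values. Set against the scanner files, it equalled the log2 processed signal plus 1 constant per array (0.290, 0.275, 0.362 and 0.356 for DMSO replicates 1 and 2 and 4-hydroxytamoxifen replicates 1 and 2), with column medians of 6.16, 6.18, 6.35 and 6.35. Its scale, centring and direction were therefore known, and it served as an alternative.

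Each array held 43379 spots and 41174 different probes without controls, and 245 probes were spotted 10 times. The share of spots well above background was 62.7% and 62.4% in the DMSO arrays and 65.9% and 62.1% in the 4-hydroxytamoxifen arrays. No spot was saturated (0 on each array). The lowest signal well above background lay between 15.0 and 19.5, against a 75th percentile between 705 and 744. The number of arrays, 2 per group, limits the precision. All 4 arrays sat on 1 slide and were read in 1 scan, with DMSO at positions 1 and 3 and 4-hydroxytamoxifen at positions 2 and 4.

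The main values were log2 processed signals minus each array's 75th percentile, after control spots and outlier spots (60 to 71 per array) had been left out and spots of one probe averaged. Probes well above background on at least 2 of the 4 arrays were kept, 26392 in all. The probe with the highest mean over the 4 arrays stood for its gene, which left 17537 features, 15139 of them with a gene symbol. Accessions and symbols of the files were matched to current names through a RefSeq table of assembly GRCm38.p6, used for names only: 33649 of 41174 probes matched, and 7525 kept the name in the file. Coordinates are those of the files, on mm9. Of 3793 genes with at least 2 called probes, 531 had probes called in opposite directions (14.0%).

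Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term), and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Averages of repeated spots differed between arrays of a group by 1.57 times (DMSO) and 1.60 times (4-hydroxytamoxifen) the noise between spots. The arrays of a group were counted as separate samples because the labels number them as such; this ratio does not tell separate cultures from repeat labelling of one RNA. Equal replicate numbers were not taken as pairs. With 2 arrays against 2, an exact permutation test cannot give a two-sided p under 0.333, so each p rests on the spread that limma pools over genes. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 22 lists; camera with an estimated correlation and fry were alternatives. For a gene not well above background on either array of a group, only a bound is given: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal, on normalized log2 values. Such genes have no order among themselves.

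The 22 lists, and the genes to name, were fixed before the data were examined: Nanos2, the 15 genes with a symbol and the largest difference in each direction among those past the threshold whose arrays did not overlap between groups, and up to 4 passing members with the largest difference in each list. Where fewer than 2 members of a list passed, the rule took the 2 with the largest difference, which did not arise. A ranking restricted to genes well above background on all arrays was chosen after the data were seen, as was a test of the lists without the fibroblast markers. Genes named beyond these rules, mostly members that moved against the rest of their list, were chosen after their values were seen. A few genes that the rules name are not reported here. Alternatives covered normexp background correction (offset 50), quantile, median and spike-in scaling, the deposited value table, other filters and probe rules, another variance prior, a replicate block, each array left out in turn, and other thresholds.

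The same code was tested on simulated arrays for the comparison of 4-hydroxytamoxifen with DMSO, over 17537 features. It called 2 of 67 genes changed by 0.5 on the log2 scale (2.98%), 35 of 67 changed by 1 (52.2%) and 58 of 66 changed by 2 (87.9%), with 9 of 17312 unchanged genes called. There 17312 of 17537 genes were unchanged, but 69.5% of features passed in the data. The adjusted threshold was thus stricter in the simulation, and these shares are not the recovery rates of the real comparison. Plots were drawn with matplotlib.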

Results

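The series asked which transcripts change when Nanos2, an RNA-binding protein that keeps spermatogonial stem cells undifferentiated, is forced on in cultured mouse germline stem cells. There were 2 arrays of cells given DMSO, the control, and 2 arrays of cells given 4-hydroxytamoxifen, the compound that activates the recombinase and so the Nanos2 construct. Values are log2 differences, 4-hydroxytamoxifen minus DMSO, with the standard error of the limma fit and 2 arrays per group. Both groups carried the construct, and no group took the compound without it, so the comparison holds the effects of Nanos2, the compound and the recombinase together.

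Nanos2 itself rose 2.93-fold, by 1.55 ± 0.10 on the log2 scale (limma adjusted p = 0.000868). Its probe, at chromosome 7, positions 19573771 to 19573830 of mm9, read 352.8 and 351.7 in the DMSO arrays and 903.8 and 1070 in the 4-hydroxytamoxifen arrays. Whether this 60-nucleotide probe lies in the part of the transcript that the construct carries was not determined here, so the value may count the endogenous gene, the construct or both.

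**Figure D1:**
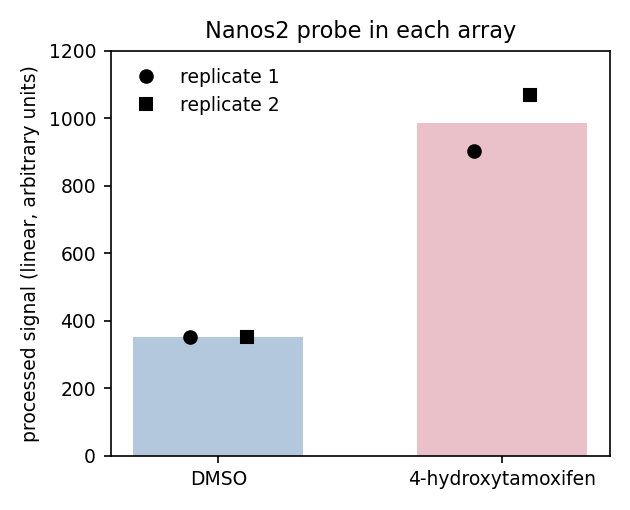
Processed signal of the Nanos2 probe (linear, arbitrary units) in each array, with bars for the mean of the 2 arrays of a group and points for the replicates. Both DMSO arrays lie near 352, and the 4-hydroxytamoxifen arrays lie at 903.8 and 1070.

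The cells given 4-hydroxytamoxifen lost transcripts of cell division and of the spermatogonial programme. Transcripts of p53 targets, fibroblast markers, macrophage and blood markers and retinoic acid response genes were higher. The retinoic acid list passed narrowly (camera adjusted p = 0.0477), and its call and that of the macrophage and blood list were each lost under some processing alternatives. Among the 22 gene lists, mitosis genes had the lowest median, -2.22, and 27 of 28 measured members fell. Spermatogonial genes of both the stem cell and the differentiating lists fell, led by Nanos3 at -4.77 ± 0.13, the germ cell paralogue of Nanos2. Dnmt3l, a cofactor of DNA methylation in germ cells, rose by 4.06 ± 0.08. No list call held when camera estimated the correlation between genes (adjusted p = 0.457 at the lowest), as given beside each list. With 2 arrays per group this version could hardly pass any list: even the mitosis list had an unadjusted camera p of 0.144. Its failures therefore do not tell moved lists from unmoved ones.

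Of 17537 features tested, 7060 were higher and 5135 lower in 4-hydroxytamoxifen cells at a limma adjusted p under 0.05, which is 69.5% of all. A difference of at least 2-fold was met by 2834 of the higher and 1437 of the lower ones, and at least 4-fold by 536 and 264. The arrays of the groups did not overlap for 15168 features (86.5%), where chance gives 33.3%. Arrays of one group correlated across probes at 0.996 (DMSO) and 0.997 (4-hydroxytamoxifen), and arrays of different groups at 0.948 to 0.954; genes are not independent replicates. The median over all features was 0.11, and -0.04 when arrays were scaled on spike-in probes, so small differences in either direction depend on the scaling.

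Among the genes with the largest rises, several were below or near background in DMSO. Adcy1, an adenylyl cyclase, rose at least 31.2-fold, Pla2g12b at least 19.1-fold, Mro at least 14.5-fold and Cfap44, a protein of the sperm flagellum, at least 13.7-fold. A second Adcy1 probe, also not well above background in DMSO, differed by 1.24 on the log2 scale, a value that background limits. The bound of 31.2-fold thus rests on 1 probe. Sybu rose at least 8.13-fold, Il18r1 at least 6.60-fold, Alpk3 at least 4.94-fold and 4933402E13Rik at least 4.76-fold. Mlana, a melanosome protein, was measured in both groups and rose by 5.47 ± 0.07 (adjusted p = 0.000369), and 0610040J01Rik rose by 4.93 ± 0.15. Cibar2 rose by 4.58 ± 0.07, Bhmt2 by 4.40 ± 0.14 and Mybpc2, a myosin-binding protein of fast muscle, by 4.32 ± 0.14. Igfbp1 (5.10 ± 0.11) and Vit (4.33 ± 0.19) were well above background on 1 of the 2 DMSO arrays.

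In a ranking limited to genes well above background on all 4 arrays, chosen after the data were seen, Thbs4 followed at 4.16 ± 0.08, then Pcnx2 at 4.13 ± 0.09, the sodium channel Scn8a at 4.11 ± 0.06 and Dnmt3l at 4.06 ± 0.08. Abcg5 (3.97), Bfsp2 (3.95), Cfap57 (3.85), Phyhip (3.83), Cacna1s (3.81) and Hc (3.62) completed it. A second Thbs4 probe gave 2.82. The Bfsp2 value, with a standard error of 0.53, was 4.70 without DMSO replicate 1 and 3.20 without DMSO replicate 2.

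Among the largest falls, Adcy10, the soluble adenylyl cyclase, fell at least 25.4-fold and the histone gene H3c1 at least 25.3-fold. Dmrtb1, a spermatogonial transcription factor, fell at least 12.4-fold by its brightest probe. A second Dmrtb1 probe, also not well above background in 4-hydroxytamoxifen, differed by -1.22 on the log2 scale, a value that background limits. Shisa3 fell at least 8.45-fold, St8sia3 at least 7.57-fold and Tril at least 3.86-fold. Among genes measured in both groups, the linker histone genes H1f5 (-4.94 ± 0.14) and H1f1 (-3.83 ± 0.07) fell, as did Asb9 (-4.91 ± 0.10), Pde4c (-4.61 ± 0.13), Dab1 (-4.36 ± 0.10) and the ETS factor Erg (-4.29 ± 0.12). Other Dab1 probes gave -3.88 to -1.42. Aurkb, a mitotic kinase, was at -3.94 ± 0.08 and Sohlh2, a factor of spermatogonial differentiation, at -3.79 ± 0.09. The ranking limited to genes above background on all 4 arrays also held Ccna2 (-3.71), Eppin (-3.69), Kif11 (-3.68), 1700013H16Rik (-3.51) and Lrr1 (-3.51).

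Genes of the spermatogonial stem cell list fell: 18 of 26 measured members were lower and 3 higher, both over all genes and adjusted over the list alone, with a median of -0.92, or -0.79 with Ret at its bound (camera adjusted p = 7.3e-05, adjusted p = 0.457 with an estimated correlation). Lhx1 fell by 2.54 ± 0.13, Nefm by 2.47 ± 0.13, Gfra1, the co-receptor of GDNF, by 2.45 ± 0.06 and Pax7 by 2.04 ± 0.11. Of further members chosen after their values were seen, Ret, the GDNF receptor kinase, fell at least 1.26-fold to below background, and Pou5f1 was at -1.85, Etv5 at -0.86 and Id4 at -0.72. Utf1 (0.90), Mcam (0.36) and Tspan8 (0.29) were the 3 that rose. The last 2 of these did not pass with spike-in scaling or without replicate 2 of either group, nor Tspan8 with a replicate block. Fibroblast and macrophage markers were higher in the same arrays, with medians of 0.90 and 0.85. The list called macrophage here and below also holds haemoglobin and endothelial genes.

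The differentiating spermatogonia list fell as well, with 21 of 28 measured members lower and 4 higher, the same counts adjusted over the list alone, and a median of -0.73 (camera adjusted p = 0.00012, adjusted p = 0.457 with an estimated correlation). Besides Nanos3, Dmrtb1 and Sohlh2, Dmrt1, a factor that controls the entry into meiosis, fell by 3.11 ± 0.10. Taf7l (-2.24), the stem cell factor receptor Kit (-0.66) and Stra8 (-0.64), a retinoic acid target required for meiosis, were lower, chosen after their values were seen. Ly6k (1.85), Prdm1 (1.58), Prss50 (1.19) and Crabp1 (0.54) were the 4 that rose, Crabp1 without passing under spike-in scaling. Embryonic fibroblast markers, described with the other cell types, were higher in the same arrays with a median of 0.90.

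Germline RNA-binding protein genes were lower in 14 of 24 cases and higher in 4, also adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.0033, adjusted p = 0.457 with an estimated correlation). Nanos3 led, followed by Nanos1 at -2.80 ± 0.12, Lin28a at -1.73 ± 0.11 and Elavl2 at -1.46 ± 0.11. Dazl, a translational regulator of germ cells, was at -1.41. Adad1 (1.09), Igf2bp2 (1.06), Fmr1 (0.33) and Fxr1 (0.24) were higher. The calls of Fmr1 and Fxr1 were not stable: both were lost with spike-in scaling and without DMSO replicate 2 or either 4-hydroxytamoxifen replicate, Fxr1 also without DMSO replicate 1. The mean of all Fmr1 probes was -0.030 and did not pass, and that of all Fxr1 probes was lower at -0.47 (limma adjusted p = 0.0243, alternatives from 0.0020 to 0.75). Genes of mRNA decay and P bodies, the machinery that removes poly(A) tails and caps, were lower in 17 of 30 cases and higher in 2, also adjusted over the list alone. Their median was -0.28 (camera adjusted p = 0.00327, adjusted p = 0.457 with an estimated correlation). Housekeeping genes had a similar median of -0.22 (6 of 12 lower, 2 higher), and the decay list was not set against random lists of like signal. A fall particular to the decay machinery is thus not shown. Pan2 fell by 1.27 ± 0.08, Edc3 by 1.07 ± 0.09, Lsm14a by 1.06 ± 0.08 and Dnd1, which binds NANOS2, by 0.88 ± 0.09. Tob1 (0.71) and Cnot6 (0.39) rose, although Cnot6 did not pass with spike-in scaling, and the mean of all its probes was -0.24 and did not pass. Fibroblast and macrophage markers (medians 0.90 and 0.85) were higher in the arrays where these lists were lower.

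Cell cycle genes fell with the largest medians. In the G1/S and replication list 22 of 25 members were lower and 1 higher, also adjusted over the list alone, with a median of -1.37 (camera adjusted p = 9.8e-08, adjusted p = 0.457 with an estimated correlation). Chaf1b, a histone chaperone subunit, fell by 2.72 ± 0.08, Cdc6 by 2.55 ± 0.06, Cdc45 by 2.45 ± 0.11 and Uhrf1 by 2.37 ± 0.09. The exception that rose was Ccnd1, cyclin D1, at 1.19. In the G2/M and mitosis list 27 of 28 members were lower and 0 higher, also adjusted over the list alone, with a median of -2.22 (camera adjusted p = 5.3e-13, adjusted p = 0.457 with an estimated correlation). Aurkb, Ccna2, Kif11 and Ccnb2 (-3.43 ± 0.07) led, and Mki67, a marker of cycling cells, was at -3.25. Cdc25b, at 0.04, did not pass. These falls also came with higher fibroblast and macrophage markers (medians 0.90 and 0.85).

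Targets of p53 rose: 21 of 26 were higher and 3 lower, also adjusted over the list alone, with a median of 0.85 (camera adjusted p = 0.00327, adjusted p = 0.616 with an estimated correlation). Perp rose by 1.63 ± 0.12, the death receptor Fas by 1.51 ± 0.11, Eda2r by 1.43 ± 0.07 and Ccng1 by 1.40 ± 0.12. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 1.04 and Bbc3 by 1.26, both chosen after their values were seen. Ddb2 (-0.88), Bax (-0.37) and Gtse1 (-0.30) were lower, and neither Bax nor Gtse1 passed without DMSO replicate 1 or without 4-hydroxytamoxifen replicate 1. Bax was also lost without DMSO replicate 2, and Gtse1 without 4-hydroxytamoxifen replicate 2, with spike-in scaling and with a replicate block. Fibroblast and macrophage markers were higher in the same arrays, with medians of 0.90 and 0.85.

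Retinoic acid response genes were higher in 9 of 14 cases and lower in 1, also adjusted over the list alone, with a median of 0.98, or 0.80 with Cyp26a1 at its bound (camera adjusted p = 0.0477, adjusted p = 0.457 with an estimated correlation). Tgm2 rose by 1.87 ± 0.06 and Rdh10, which makes retinal, by 1.57 ± 0.07; other Tgm2 probes gave 0.44 to 0.99. Cyp26a1, which degrades retinoic acid, was not well above background in DMSO and rose at least 1.71-fold. The gene that fell was Stra8. Fibroblast and macrophage markers were higher in the same arrays, with medians of 0.90 and 0.85. The list did not pass with normexp correction (camera adjusted p = 0.0534), with the filter on all 4 arrays (0.0635) or with the mean of a gene's probes (0.067). Nor did it pass without 4-hydroxytamoxifen replicate 2. Adjusted p over the alternatives ran from 0.00466, given by fry, which does not compare the list with other genes, to 0.457, given by camera with an estimated correlation.

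Markers of other cell types moved in the same comparison. Embryonic fibroblast markers, listed because the cells had grown on feeders that were removed before RNA extraction, were higher in 31 of 32 cases over all genes and in 32 adjusted over the list alone. Their median was 0.90 (camera adjusted p = 2.9e-06, adjusted p = 0.616 with an estimated correlation). Thbs1 rose by 1.48 ± 0.11, Pdgfrb by 1.40 ± 0.07, Twist2 by 1.30 ± 0.09 and Fbln5 by 1.26 ± 0.08, while the collagen gene Col1a1, at 0.26, did not pass over all genes, though it did with quantile normalization and without DMSO replicate 2. Macrophage and blood markers were higher in 12 of 17 cases and lower in 0, also adjusted over the list alone, with a median of 0.85 (camera adjusted p = 0.0108, adjusted p = 0.494 with an estimated correlation). Hba-a1 rose by 1.44 ± 0.06, Adgre1 by 1.40 ± 0.14, Aif1 by 1.39 ± 0.10 and Tek by 1.16 ± 0.09. That list did not pass with spike-in scaling (camera adjusted p = 0.0516, alternatives from 0.00188 to 0.494). Sertoli and Leydig markers were higher in 6 of 10 cases and lower in 2, also adjusted over the list alone, and the list did not pass (median 0.84, camera adjusted p = 0.33). Cldn11, a tight junction protein, rose by 3.58 ± 0.11, Dhh by 1.33 ± 0.09, Clu by 1.22 ± 0.06 and Inhbb by 1.04 ± 0.10, while Wt1 (-0.88) and Cyp17a1 (-0.43) were lower, Cyp17a1 without passing when DMSO replicate 1 or 4-hydroxytamoxifen replicate 1 was left out. A second Inhbb probe gave 0.07.

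**Figure D2:**
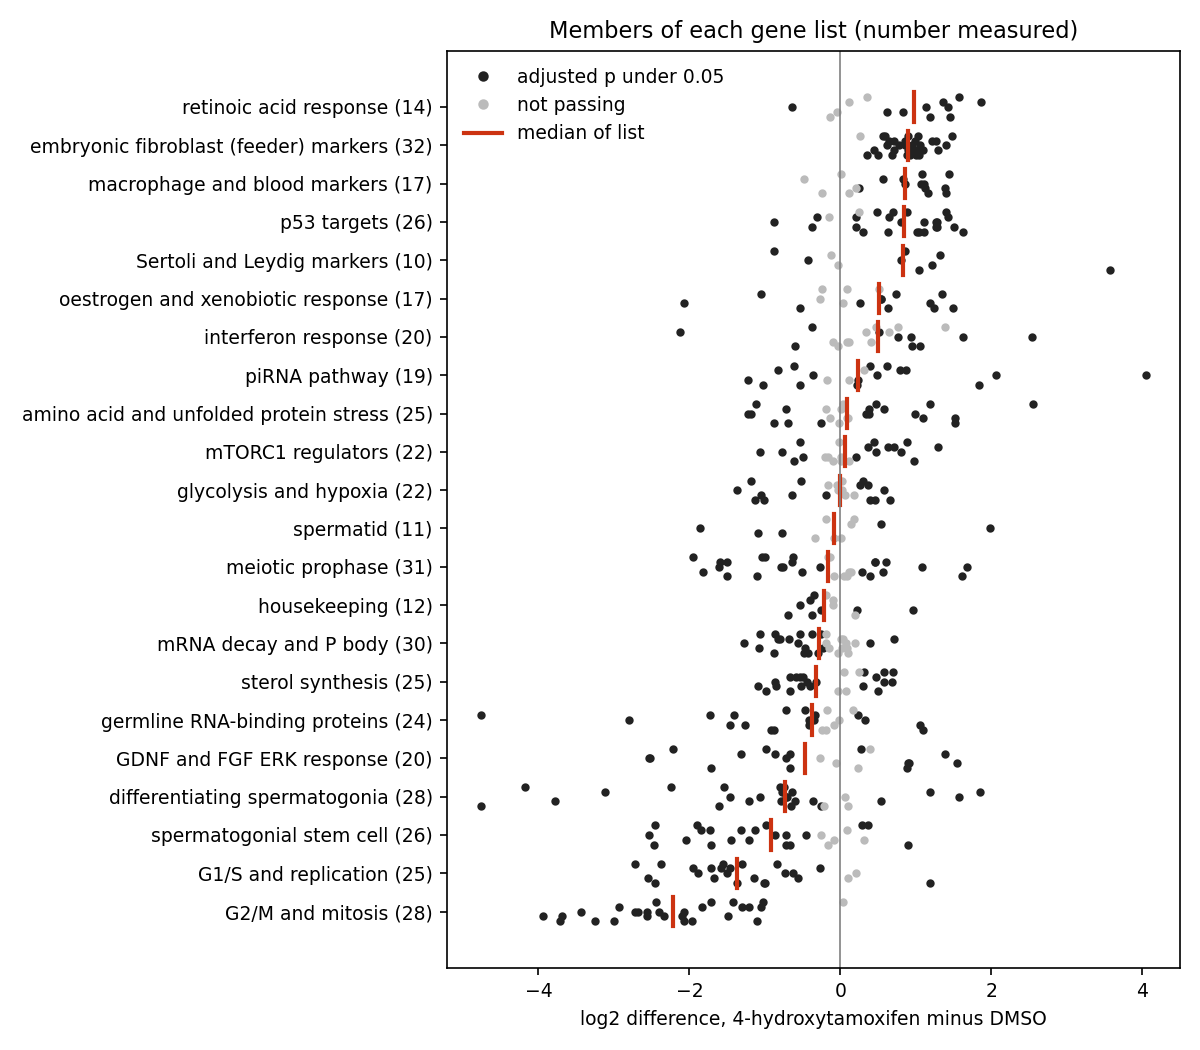
Log2 difference, 4-hydroxytamoxifen minus DMSO, of each measured member of the 22 gene lists, ordered by list median (red line), with members past a limma adjusted p of 0.05 in black and the others in grey. The mitosis list lies farthest to the left, with a median of -2.22, and 31 of the 32 fibroblast markers are black and to the right of 0.

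Genes of the piRNA pathway, which silences transposons in germ cells, went both ways: 10 of 19 were higher and 6 lower, also adjusted over the list alone (median 0.24, camera adjusted p = 0.56). Dnmt3l rose by 4.06 ± 0.08, Tdrd9 by 2.06 ± 0.08 and Piwil4, a nuclear PIWI protein, by 1.84 ± 0.07, and Pld6 fell by 1.22 ± 0.06. The germ cell helicase Ddx4 was at -0.17 and did not pass, though it did with normexp correction. Meiotic prophase genes were lower in 15 of 31 cases and higher in 9, also adjusted over the list alone (median -0.16, camera adjusted p = 0.0761). The list passed as lower with spike-in scaling (median -0.30, adjusted p = 0.0344), with no filter on dim probes (-0.21, 0.0115) and without DMSO replicate 2 (-0.18, 0.0467), within a range of 0.0115 to 0.666 over all alternatives. Meiob fell by 1.95 ± 0.08 and the recombinase gene Dmc1 by 1.82 ± 0.15, while Dpep3 rose by 1.67 ± 0.14 and Rnf212 by 1.62 ± 0.06. Of 11 spermatid genes, 2 were higher and 3 lower, also adjusted over the list alone (median -0.09, camera adjusted p = 0.56): Tekt1 rose by 1.99 ± 0.09 and Tnp1 by 0.54, Izumo1 fell at least 2.51-fold, Spaca1 fell by 1.09 ± 0.07 and Hspa1l by 0.77 ± 0.16. Tnp1 did not pass with spike-in scaling, nor Hspa1l without 4-hydroxytamoxifen replicate 1.

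Genes that respond to GDNF and FGF through ERK did not pass as a list, with 10 of 20 lower and 6 higher, also adjusted over the list alone (median -0.47, camera adjusted p = 0.133). It passed as lower with spike-in scaling (median -0.62, camera adjusted p = 0.0344). Adjusted p over the alternatives ran from 0.0186, given by fry, which does not compare the list with other genes, to 0.697, given by camera with an estimated correlation. Lhx1 fell by 2.54 ± 0.13, Etv4 by 2.52 ± 0.10, Mycn by 2.21 ± 0.07 and Bcl6b by 1.71 ± 0.11, whereas Myc (1.38) and Etv1 (1.55) rose. Of 22 mTORC1 regulators, 10 were higher and 5 lower, also adjusted over the list alone (median 0.06, camera adjusted p = 0.703), and the median turned to -0.09 with spike-in scaling. Ddit4l rose by 1.30 ± 0.08, Rragc by 0.98 ± 0.06 and Tsc1, an mTORC1 inhibitor, by 0.89 ± 0.07. Ddit4, another inhibitor, fell by 1.06 ± 0.24, as did Eif4ebp2 (-0.78), Akt1s1 (-0.62), Rptor (-0.53) and Castor1 (-0.49). Ddit4 did not pass without either 4-hydroxytamoxifen replicate, Akt1s1 without either DMSO replicate, and Castor1 without DMSO replicate 2 or 4-hydroxytamoxifen replicate 1.

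Of 25 sterol synthesis genes, 13 were lower and 8 higher over all genes, and 13 and 9 adjusted over the list alone (median -0.33, camera adjusted p = 0.227). Cyp51 fell by 1.09 ± 0.07, Idi1 by 0.98 ± 0.06 and Fdps by 0.86 ± 0.10. Amino acid and unfolded protein stress genes were higher in 11 of 25 cases and lower in 7, also adjusted over the list alone (median 0.09, camera adjusted p = 0.798). The cystine transporter gene Slc7a11 rose by 2.56 ± 0.09, with 1 of 2 DMSO arrays above background, Nupr1 by 1.52 ± 0.12 and Ddit3 by 1.52 ± 0.07, and Shmt2 fell by 1.23 ± 0.11. Oestrogen and xenobiotic response genes, listed because 4-hydroxytamoxifen binds oestrogen receptors, were higher in 9 of 17 cases over all genes, 10 adjusted over the list alone, and lower in 3 (median 0.52, camera adjusted p = 0.449). Abcb1b rose by 1.49 ± 0.09, Nrip1 by 1.35 ± 0.10 and Cyp1b1 by 1.24 ± 0.10. The oestrogen receptor gene Esr1 fell at least 2.29-fold, and Gclm (-1.05) and Tiparp (-0.53) were lower.

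Glycolysis and hypoxia genes were higher in 7 of 22 cases and lower in 8, also adjusted over the list alone (median -0.01, camera adjusted p = 0.33). Ankrd37 fell by 1.36 ± 0.06, Hk2, the first enzyme of glycolysis, by 1.18 ± 0.06, Egln3 by 1.13 ± 0.06 and Ndrg1 by 1.05 ± 0.07. Of 12 housekeeping genes, 6 were lower and 2 higher, also adjusted over the list alone (median -0.22, camera adjusted p = 0.13). The list passed with no filter on dim probes (camera adjusted p = 0.04996). Adjusted p was 0.00554 with fry, which does not compare the list with other genes, and 0.494 with camera at an estimated correlation. Actb fell by 0.69 ± 0.07, Sdha by 0.53 ± 0.07 and Tbp by 0.40 ± 0.06, and B2m (0.96 ± 0.11) and Rplp0 (0.22) rose. Other probes of Sdha gave 0.04 and 0.07, and Rplp0 did not pass with spike-in scaling (limma adjusted p = 0.807, alternatives from 0.00171), nor with quantile normalization, the mean of its probes, no filter on dim probes, a replicate block or any 1 array left out.

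Interferon response genes did not pass as a list, with 7 of 20 higher and 3 lower, also adjusted over the list alone (median 0.50, camera adjusted p = 0.464). Ifit2 rose by 1.62 ± 0.16 and Ifih1 by 1.06 ± 0.20. Ifi27l2a fell by 2.13 ± 0.11, and Oasl2 (-0.59) and Irf1 (-0.37) were lower. Neither of these last 2 passed without 4-hydroxytamoxifen replicate 1, Irf1 also not without replicate 2 of that group or DMSO replicate 1, and Ifih1 not without 4-hydroxytamoxifen replicate 2. The 2 DMSO arrays differed in this list: all 20 members were lower in DMSO replicate 2, by a median of -0.50, and Cxcl10 by -2.56. Without DMSO replicate 2 the list median was -0.11 (camera adjusted p = 0.597), and without DMSO replicate 1 it was 1.09 (camera adjusted p = 0.00536). Over all alternatives the adjusted p of the list ranged from 0.00536 to 0.843.

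**Figure D3:**
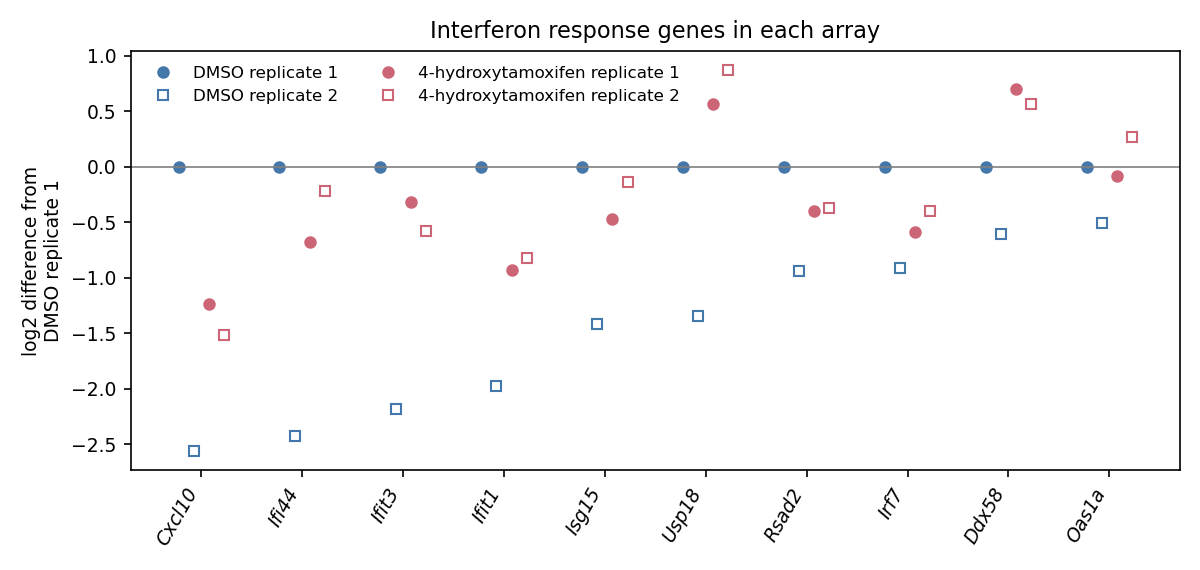
Log2 difference of each array from DMSO replicate 1 for the 10 interferon response genes that differed most between the DMSO arrays, with circles for replicate 1, squares for replicate 2, blue for DMSO and red for 4-hydroxytamoxifen. The genes shown lie under 0 in DMSO replicate 2, from -0.51 for Oas1a down to -2.56 for Cxcl10.

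Over the 22 lists, 10 passed with camera at the preset correlation, 4 higher and 6 lower, and 0 passed with an estimated correlation. With fry, which tests whether a list's genes move one way and does not compare them with other genes, 20 passed.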

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

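Nanos2 was higher under every alternative run, between 1.39 (normexp) and 1.67 (without 4-hydroxytamoxifen replicate 1), and passed in each. Counts moved most with the threshold: 2834 genes higher and 1437 genes lower at 2-fold or more, against 7060 and 5135. With every probe tested, 9542 probes were higher and 8207 lower, because more features were counted. The gene lists moved fell from 10 to 0 when camera estimated the correlation and rose to 20 with fry; the other settings gave 9 to 12. Leaving out 1 array gave 5887 to 6760 higher and 4125 to 4667 lower, 9 to 11 lists, and a Nanos2 difference of 1.43 to 1.67.

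Scaling on 7 spike-in probes moved the median of all features from 0.11 to -0.04 and gave 4815 higher and 4782 lower (50.2% higher, against 57.9%). The spike-in probes differed by 0.27 between the DMSO arrays, more than the 0.08 between groups. Of the 12195 calls, 9143 remained under this scaling and 0 turned. The largest number that turned was 73, with the mean of a gene's probes.

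With the replicate number as a replicate block, 6496 genes were higher and 4551 lower, the Nanos2 difference was 1.55 (limma adjusted p = 0.00287, where alternatives ranged from 1.28e-09 to 0.00934), and 10 lists passed. Deviations of arrays with one number correlated at -0.05 across genes. This value, from 1 pair of differences, does not tell whether arrays with equal numbers shared a culture or day. A slide block was not run, because 1 slide and 1 scan held all arrays.

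Lists or genes that changed direction were few, and the cause was not tested except where a gene's probes conflicted. The interferon median was -0.11 without DMSO replicate 2 and 1.09 without DMSO replicate 1. The mTORC1 median was -0.088 with spike-in scaling and -0.10 with the mean of probes. Cdc25b was -0.11 with spike-in scaling. With the mean of probes, Cnot6 was -0.24, Fmr1 -0.030, Fxr1 -0.47 and H1f3 -0.36. Other probes of these genes ran against the brightest one: -0.99 to -0.11 for Cnot6, -0.39 for Fmr1, -0.99 to -0.65 for Fxr1 and -1.76 for H1f3. With normexp H1f3 was -1.05, and whether another probe was then the brightest was not checked. Of the other results for named genes, 2683 kept direction and side of the threshold, 76 no longer passed and 11 newly passed. For lists these numbers were 339, 15 and 16. With the fibroblast markers taken out, chosen after seeing the data, 9 lists passed. Differences of dim genes are limited by signal over background: the lowest signal well above background was 36.1 to 47.0 times under the 75th percentile.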

Other observations

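All tests in this part were chosen after the results they bear on had been seen, and lists of axoneme, sarcomere and histone genes were written without the genes that had already been named.

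Genes of the axoneme and motile cilium, the microtubule core of cilia and sperm tails, were higher in 41 of 53 cases and lower in 5, and 42 and 6 adjusted over the list alone, with a median of 0.81. The camera adjusted p over the 3 lists of this part was 3.5e-05, and adjusted p = 0.286 with an estimated correlation. Spag17, of the central pair, rose at least 3.88-fold, Spag6l by 2.56 ± 0.14 and Dnah9, a dynein heavy chain, by 2.35 ± 0.17. Members that fell included the regulators Foxj1 (-1.77, above background on 1 of 2 arrays in 4-hydroxytamoxifen) and Rfx3 (-0.87), with Dnah1 (-0.66, not passing without 4-hydroxytamoxifen replicate 1) and Tekt2 (-0.50). Fibroblast and macrophage markers were higher in the same arrays, with medians of 0.90 and 0.85. Because dim genes tended to rise (median 0.30 in the dimmest of 5 equal classes of features, -0.005 in the brightest), the median was set against 10000 random lists of like signal. It lay at percentile 99.99, with 95% of random medians from -0.10 to 0.46. A rise of the class is therefore a hypothesis that signal level alone does not account for.

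Sarcomere genes, the contractile proteins of muscle, were higher in 27 of 38 cases and lower in 4, also adjusted over the list alone, with a median of 0.87, or 0.78 with genes below background at their bounds. The camera adjusted p was 0.00242, and adjusted p = 0.286 with an estimated correlation. This rise was about that of the fibroblast and macrophage markers (0.90 and 0.85), and a shared source was not tested. Neb rose by 2.43 ± 0.13 (other probes 0.23 to 2.09), Ckm at least 1.59-fold and Ttn, the giant spring protein, by 1.94 ± 0.11, while Atp2a1 (-1.66), Actn2 (-1.07), Myl2 (-0.59) and Tnni3 (-0.25) fell, Tnni3 without passing when any 1 array was left out, with spike-in scaling, with no filter on dim probes or with a replicate block. The median lay above those of all 10000 random lists of like signal (percentile 100, 95% of random medians from -0.15 to 0.51). Replication-dependent histone genes other than H3c1, H1f5 and H1f1 went both ways, with 14 of 26 lower and 10 higher, also adjusted over the list alone. Their median of -0.25 lay at percentile 1.68 of random lists, but the list did not pass with camera (adjusted p = 0.111, adjusted p = 0.339 with an estimated correlation). H2ac15 fell by 2.44 ± 0.06 and H2ac23 by 2.40 ± 0.06, and H2bc4 (1.15) rose. H1f3 was higher by its brightest probe (1.05), but a second probe gave -1.76, so its direction is unclear. With normexp correction H1f3 was at -1.05.

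Between the DMSO arrays, interferon response genes differed by a median of -0.50, replicate 2 minus replicate 1, and between the 4-hydroxytamoxifen arrays by 0.13. Fibroblast markers went the other way between the DMSO arrays, with a median of 0.16 and 1 of 32 lower in replicate 2. So did ERK response genes (0.22, 2 of 20 lower), Sertoli and Leydig markers (0.13, 3 of 10 lower) and p53 targets (0.10, 4 of 26 lower). Spermatid genes were lower in DMSO replicate 2 (-0.13, 9 of 11 lower). Smaller falls there were seen for mitosis (-0.06, 23 of 28 lower), differentiating spermatogonia (-0.06, 20 of 28), meiotic prophase (-0.04, 23 of 31) and piRNA genes (-0.06, 15 of 19). Spermatogonial stem cell genes did not share these falls (0.05, 8 of 26 lower).

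Higher fibroblast markers may come from more feeder cells left in the 4-hydroxytamoxifen samples, even though feeders had been removed, or from a lower share of germ cells that raised other cell types alike. The fibroblast median exceeded that of the macrophage and blood list by 0.048. The 95% bootstrap interval of this difference, from -0.30 to 0.71, was too wide to decide for or against either. Counts of markers more than 2 standard errors from a common median (16 of 32 for fibroblasts, 30 of 49 with macrophages) were run too and set aside, since these standard errors may hold technical spread only. All 32 fibroblast markers lay above 0, from 0.26 for Col1a1 to 1.48 for Thbs1. Changes inside the feeder cells, or expression of these genes by the germ cells, were not tested.

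The fall of the spermatogonial lists could come from a lower share of germ cells. That share would lower germ cell genes of the piRNA pathway too, yet their median was 0.24 (95% bootstrap interval -0.36 to 0.62), against -0.76 over the 54 genes of both spermatogonial lists. A lower share alone would shift genes made only by germ cells by a common amount. Quartiles ran from -1.73 to -0.18 (stem cell), -1.48 to -0.25 (differentiating) and -0.45 to 0.71 (piRNA). This spread argues against a lower share as the whole cause over these lists. Whether each member is made only by germ cells was not tested. The piRNA comparison was chosen after the piRNA median had been seen, and the piRNA list's members moved both ways (10 of 19 higher, 6 lower). The piRNA list is therefore no steady gauge of the share of germ cells, and a lower share may add to the fall. An effect of 4-hydroxytamoxifen or the recombinase, in place of Nanos2, cannot be told apart from one of Nanos2, because 0 groups took the compound without the construct. An effect of Nanos2 is the biological explanation that the design names, and it stays untested for the same reason.

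The fall of the cell cycle lists could come from a larger share of feeder cells, which do not divide. Dilution by such cells would lower piRNA pathway genes alike, and their median of 0.24, with an interval from -0.36 to 0.62, lay above the -1.71 of the 53 cell cycle genes. The piRNA list is no steady gauge of dilution, since its members moved both ways (10 of 19 higher, 6 lower) and its median was already known. Medians of the stem cell (-0.92) and differentiating (-0.73) spermatogonial lists also lay above -1.71. Upper quartiles of the G1/S (-0.73) and mitosis (-1.47) lists lay under the lower quartile of the piRNA list (-0.45). Lower quartiles of the stem cell (-1.73) and differentiating (-1.48) lists overlapped with the cell cycle lists, but lay above the mitosis median of -2.22. The cell cycle genes thus fell more than these germ cell lists, which argues against dilution as the whole cause of their fall. Dilution may still add to it. A response to the recombinase stays open beside one to Nanos2; p53 targets rose in the same arrays (21 of 26), and so did fibroblast markers (median 0.90).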
